A study of Mus musculus with 12 samples.

How the data were processed

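The study measured RNA in mouse liver epithelium with 2 assays. The 6 single-cell libraries were made from 1 mouse each: biliary epithelial cells (BEC) of 3 healthy mice, BEC of 1 mouse on DDC diet, hepatocytes (HEP) of 1 healthy mouse and HEP of 1 mouse on DDC diet. Per the labels, the adult C57Bl/6 livers were perfused with collagenase, hepatocytes were removed from the BEC preparations by low-speed centrifugation, and libraries were made by inDrops, a droplet method. The 6 bulk samples held cells of female C57Bl/6 mice sorted as EpCAM-positive and negative for CD45, CD11b and TER119. Controls carried floxed Yap with tetO-Cre, and knockouts carried the same alleles plus the CAGs-rtTA3 activator, which the controls lacked. Doxycycline was given at 1 mg/ml for 7 days, and cells were isolated at day 14 (3 samples in each group). The sex of the single-cell mice is not given in the sources used here.

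The deposited bulk table holds normalised counts (a signal, not raw counts) for 23337 genes in 6 columns, whose names match the knockout titles but give only the group of the controls, since the 3 control titles carry the same number; samples are numbered here in column order. The authors trimmed reads with Trimmomatic 0.33, aligned them with STAR and counted them with featureCounts, and divided the counts by 1 size factor per sample. The size factors were recovered as the smallest step between values of a column, which made 100% of the values whole numbers of reads at a tolerance of 0.01. Recovered totals were about 30632200, 25719200 and 13343300 reads in controls 1 to 3 and 18978600, 24569000 and 18405300 in knockouts 1 to 3. For the single cells the authors aligned reads with BWA 0.7.10 and deposited counts per gene and barcode in 3 matrices for each library. The first matrix holds counts of distinct molecular identifiers (UMIs) and was used here. The second holds counts of reads, never below the UMI counts, at 2.18 to 7.08 reads per UMI. The last holds expected counts, in which the authors corrected UMI counts for collisions among 4096 UMIs in the BEC and 65536 in the HEP libraries; the largest gap to that formula was 4.996e-09. BEC barcodes had 16 bases and HEP barcodes 12 bases, each HEP library held exactly 6000 barcodes, and the cell types were counted against different gene sets, so cell type and library layout go together. Counters and genome build are not given in the sources used here, so genes are placed by chromosome only.

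Cells were kept with at least 500 UMIs, at least 250 genes and at most 30% mitochondrial UMIs. Of 1243, 1374, 2587 and 2284 BEC barcodes (controls 1 to 3, then DDC), 1236, 1363, 1505 and 1690 passed; of 6000 barcodes in each HEP library, 5466 (control) and 3158 (DDC) passed. Doublets were called per library with the Scrublet method in scanpy 1.11.5, which removed 6, 4, 14 and 8 BEC and 0 and 0 HEP cells. With 0 calls among 5466 and 3158 cells the caller did not work in the HEP libraries, and doublets stayed in them. In BEC it marked 0.485%, 0.293%, 0.930% and 0.473% of cells, so how many doublets it missed there is open. BEC and HEP libraries were clustered separately (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0 with leidenalg 0.10.2, seed 0). A cluster was named biliary-like or hepatocyte-like from marker lists, needing at least 3 detected markers of its class and leaving it unnamed where at least 2 markers of another class were among its 10 leading genes. Such a marker counted only if the share of cells with it differed by at least 10 percentage points from that in the other cells. Leading genes were ranked within each library, cells of the cluster against its other cells, and averaged over libraries. In a cluster of 1 mouse they therefore do not compare DDC with control cells. UMIs were then summed per library over cells of the expected class. Cell shares carry exact Clopper-Pearson 95% intervals and levels exact Poisson 95% intervals. All such intervals, and the floor of 3 counts used where a level was 0, cover counting error only.

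Comparisons, gene lists, markers, the rule for named genes and the first set of alternatives were fixed before the data were examined. Bulk groups were compared with limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend, 4 residual degrees of freedom) on log2(normalised count + 1), for genes with a mean of at least 10 over the 6 samples. BEC of the DDC mouse were compared with BEC of the 3 healthy mice, and healthy BEC with healthy HEP, by edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test) on the summed UMIs. Each of these sets 3 libraries against 1, so the spread comes from the 3 controls and the lone library is assumed to vary as they do. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The HEP libraries, 1 per group, allow no test: ratios of CPM (UMIs of a gene scaled to a common library total) are given with exact conditional binomial intervals, and the median log2 ratio of a list with its percentile among 10000 random lists matched on expression, over genes of at least 5 CPM. BEC and HEP were compared over the 13814 genes listed for both. Nothing in the labels says that the 3 bulk samples of a group are separate animals, so the limma p-values measure spread between samples only.

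Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. No list in any of the 3 tested comparisons held its call with the estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone; where 1 count is given, the other was the same. The process lists were YAP targets, Hippo components, immediate-early and dissociation genes, ER stress, bile acid synthesis and transport, biliary ion transport and cilia, haem and iron, NRF2 targets, xenobiotic P450 genes, pericentral and periportal hepatocyte genes, acute phase, chemokines and NF-kB, interferon-stimulated genes, MHC class II, cholesterol synthesis, p53 targets, cell cycle, reactive duct and matrix, the Notch pathway, and keratins and junctions. The cell type lists were biliary, hepatocyte, macrophage, neutrophil and monocyte, endothelial, stellate and mesenchymal, mesothelial, T and NK, B, dendritic and erythroid markers. Named genes were Yap1, the 12 largest rises and 12 largest falls in the bulk samples (adjusted p under 0.05, every knockout value outside the control range, mean of at least 50 in the higher group), the 12 largest each way in BEC of the DDC mouse (at least 50 CPM, outside the control range) and in HEP (at least 100 CPM and 2-fold), the 8 largest each way between cell types (at least 100 CPM), and up to 4 members of each list by smallest p or, in HEP, largest ratio at 20 CPM or more. Predicted genes without a symbol, pseudogenes and mitochondrial genes were counted and not named. Some genes that the rule named are withheld and left out of the text.

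Co-variation of YAP targets was measured within each BEC library as the mean pairwise Spearman correlation over cells thinned to 1000 UMIs, for list genes seen in at least 2% of cells, against 1000 random lists matched on expression. Alternatives were other pseudocounts, filters, normalisations and tools (edgeR and DESeq2 1.42.0 on the recovered reads), other cell filters, the other matrices, and leaving out each replicate; the closing section gives their effect. The library total without mitochondrial and rRNA-like genes and a stricter naming of clusters were added after the values were seen. The methods were tested on simulated data. With limma at 3 against 3, 63% of genes changed 2-fold and 95% of those changed 4-fold were called, with 10 false among 168 calls. With edgeR at 3 against 1 the BEC comparison recovered 17% and 81%, with 16 false among 114 calls, and the cell type comparison 16% and 79%, with 12 false among 107 calls. For HEP, 191 of 200 intervals held the simulated ratio. Those counts were drawn as Poisson, as the intervals assume, so this checks the calculation and not spread between mice or libraries. In the co-variation test a linked list lay at the 100th percentile and an unlinked list at 46.8. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 did the remaining steps.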

Results

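Liver epithelium of adult mice was profiled in 6 single-cell libraries and 6 bulk RNA samples. The single-cell libraries held biliary epithelial cells (BEC), which line the bile ducts, from 3 healthy mice and 1 mouse on DDC, a diet that injures bile ducts, and hepatocytes (HEP) from 1 healthy and 1 DDC-fed mouse. The bulk samples held sorted EpCAM-positive biliary cells of 3 control and 3 Yap1-deleted samples. The BEC libraries of the 3 healthy mice held 2296279, 1978827 and 2947880 UMIs, and that of the DDC mouse 6019741. The HEP libraries held 23030220 (control) and 13012278 (DDC) UMIs. Bulk depth ran from about 13343300 to 30632200 reads per sample. Values of 1 library have no replicate and carry 95% counting intervals; means carry SDs with n = 3.

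Most cells passing the quality filters lay in clusters named for the class of their library. Biliary-like cells made up 99.7% (99.2 to 99.9; 1226 of 1230), 99.6% (99.0 to 99.8; 1353 of 1359) and 98.7% (97.9 to 99.2; 1471 of 1491) of cells in the 3 healthy BEC libraries and 98.0% (97.2 to 98.6; 1648 of 1682) in the DDC library. Hepatocyte-like cells made up 99.5% (99.3 to 99.7; 5439 of 5466) of the control and 95.9% (95.2 to 96.6; 3030 of 3158) of the DDC HEP library. The unnamed BEC cluster (64 cells) was led by Dmbt1, Lyz1, Srgn, Vim and the endothelial marker Clec4g. The unnamed HEP cluster (128 DDC and 27 control cells) was led by Lyz2, Ctss and the Kupffer cell markers Cd5l, Clec4f and C1qb. Biliary-like cells of the DDC mouse lay almost wholly in their own clusters. The larger cluster, led by Zfp36, Cxcl1 and Ccl20, held 64.0% of DDC cells and no control cell. The smaller, led by Ctla2a, S100a6 and Lgals3, held 32.4% of DDC cells. Leading genes set a cluster against other cells of the same library, so here they describe differences among DDC cells only. Healthy biliary cells fell into clusters led by the heat-shock genes Dnajb1 and Hspa1a, by Ahsg, Apoc1 and Ttr, or by Cxcl1, Ier3 and the YAP target Ankrd1, the last holding 10.6%, 16.6% and 27.9% of cells in controls 1 to 3. The cluster led by Ahsg, with 22.3%, 27.0% and 29.9% of control cells, had the hepatocyte marker Ttr among its leading genes. Its control cells held 864 CPM of Epcam and 1086 CPM of Sox9, biliary markers, against 651 to 799 and 1117 to 1132 CPM in the other 3 control clusters named biliary-like. They also held the most Alb (6223 against 4165 to 5461 CPM) and Ttr (3690.2 against 1587 to 2907 CPM). A stricter naming, chosen after the values were seen, left unnamed any cluster with a marker of another class among its 10 leading genes. It took the name from that cluster and from a HEP control cluster led by the erythroid marker Hbb-bs, and the named shares became 77.4%, 72.6% and 68.7% in healthy BEC and 69.0% in control HEP. In HEP, cells of the 2 mice also separated, with 69.2% of DDC cells in a cluster led by mitochondrial genes and 26.8% in a cluster led by rRNA-like genes and Lars2 (median 1128 UMIs per cell). Of control cells, 30.5% lay in the cluster led by Hbb-bs and mitochondrial genes and 18.1% in another led by rRNA-like genes and Lars2 (median 3904 UMIs per cell).

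The first comparison asked how sorted biliary epithelium changed after deletion of Yap1, the transcriptional co-activator that the Hippo kinases restrain. The knockouts alone carried the CAGs-rtTA3 activator, so loss of Yap1 cannot be told apart from effects of the activator and of active Cre. Yap1 (chromosome 9) stood at 3208, 3324 and 3139.7 normalised counts in controls 1 to 3 and at 42.2, 561 and 67.3 in knockouts 1 to 3. Its mean fell from 3224 ± 93.4 to 224 ± 293, lower in 3 of 3 knockouts than in any control and 27.2-fold on the fitted log2 scale, which all bulk folds follow (limma, log2 fold change -4.77 with SE 0.82, adjusted p = 0.0154). Without knockout 3 its adjusted p was 0.0774 (range over its alternatives 0.000222 to 0.0774). Inflammatory genes were among the largest rises. Nos2, the inducible nitric oxide synthase, rose from 2.79 ± 2.25 to 293 ± 225 (log2 6.16, adjusted p = 0.00332). Ccl2, which recruits monocytes, rose from 68.9 ± 50.9 to 2531 ± 546 (log2 5.67, adjusted p = 0.00631). Cxcl5, which recruits neutrophils, rose from 53.4 ± 39.0 to 1309 ± 184 (log2 4.80, adjusted p = 0.00224). Each of these was higher in 3 of 3 knockouts than in any control.

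In all, 1179 of 13479 genes passed (647 up and 532 down; 302 and 240 by at least 2-fold), and 3415 had an unadjusted p under 0.05. The groups did not overlap for 31.6% of genes, against 10% by chance. The count was 771 without control 1, 425 without knockout 1 and 237 without knockout 3, and 1961 with DESeq2. Besides the chemokines, Il1rn, the interleukin-1 receptor antagonist, rose from 203 ± 132 to 4218 ± 994 and Cdh17, a cadherin of intestinal epithelium, from 1.27 ± 0.498 to 71.8 ± 24.7 (adjusted p = 0.00353 and 0.00224). Expi, Sectm1a, Akap12, Cpe and Ccl5 also rose, by log2 3.84 to 5.20 (adjusted p 0.00134 to 0.00538). Tbxas1, thromboxane synthase, fell from 490.4 ± 324 to 16.1 ± 10.8 (28.3-fold; adjusted p = 0.00449). Ces1c, a carboxylesterase, fell 26.2-fold from 2163 ± 1391 to 86.2 ± 67.6, Hao2, a hydroxy acid oxidase, 20.3-fold and Cldn10, a tight junction claudin, 9.60-fold from 135 ± 34.0 to 13.4 ± 4.64 (adjusted p = 0.00568, 0.00613 and 0.00408). Plcxd3 fell by 2.83 on the log2 scale (adjusted p = 0.00597).

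Among the chemokine and NF-kB genes, 10 of 15 measured members rose and 0 fell (11 rose when adjusted over the list alone; camera adjusted p = 6.62e-09, and adjusted p = 0.457 with an estimated correlation). Besides Ccl2 and Cxcl5 these included Cxcl2 (114 ± 65.6 to 879.6 ± 155) and Lif (761 ± 123 to 2469 ± 441), a cytokine of the interleukin-6 family. Of 17 reactive duct and matrix genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 1.51e-06, and adjusted p = 0.457 with an estimated correlation). Cd44 (chromosome 2), the hyaluronan receptor, rose 12.7-fold from 866 ± 259 to 10723 ± 1680.0 and the adhesion molecule Vcam1 6.88-fold from 2735 ± 744 to 18493 ± 3003 (adjusted p = 0.00134 and 0.00190). The growth factor Pdgfb rose from 1586 ± 440.4 to 4943 ± 637 and the integrin subunit Itgb6 from 872 ± 116 to 1994 ± 60.8 (adjusted p = 0.00488 and 0.00332). The 1 member that fell, chosen after its values were seen, was the intermediate filament gene Vim, from 230.2 ± 43.1 to 103 ± 10.0. Acute phase genes moved both ways, with 4 up and 1 down of 11 (the same counts adjusted over the list alone; camera adjusted p = 0.0306, and adjusted p = 0.457 with an estimated correlation). That call ended without control 2 (0.0984; range over its alternatives 0.00606 to 0.0984). Lcn2, the iron-binding lipocalin, rose from 2090.3 ± 729 to 12248 ± 2023 and the fibrinogen gene Fgb from 161 ± 29.1 to 939.8 ± 172 (adjusted p = 0.00347 and 0.00189). MHC class II genes had 2 of 5 up and 5 when adjusted over the list alone (camera adjusted p = 0.00290, and adjusted p = 0.638 with an estimated correlation), and Cd74, the invariant chain, rose from 2639.7 ± 753 to 15143 ± 6247 (adjusted p = 0.00620). Pigr, the receptor that carries IgA into bile, fell from 11286 ± 132 to 4899 ± 350.5 (adjusted p = 0.00189), the 1 periportal gene of 11 that changed (camera adjusted p = 0.685).

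The YAP target list did not move as a group in the knockout: 2 of 21 measured members rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.804, and adjusted p = 0.916 with an estimated correlation). Rbms3 fell from 5005 ± 469 to 3179.9 ± 486 and the kinase gene Nuak2 from 1114 ± 85.6 to 761 ± 98.7 (adjusted p = 0.0238 and 0.0352). The receptor kinase Axl rose from 34.3 ± 13.2 to 127 ± 24.2 and Tgfb2 from 2553 ± 580.4 to 4389.9 ± 443 (adjusted p = 0.0125 and 0.0310). Each of these calls ended when 1 or another sample was left out. The calls of Rbms3, Nuak2 and Tgfb2 also ended without the trend in limma (0.0541, 0.0676 and 0.0682). The Rbms3 call ended without control 1 (0.0598), knockout 1 (0.0816) or knockout 3 (0.118). That of Axl ended without knockout 1 (0.0535) or knockout 3 (0.0713), and that of Tgfb2 ended without knockouts 1, 2 or 3 (0.0927, 0.0785 and 0.0990). Nuak2 lost its call without any 1 of the 6 samples (0.0825, 0.0729 and 0.0533 without controls 1 to 3 and 0.0978, 0.0606 and 0.0979 without knockouts 1 to 3). Over all alternatives adjusted p ranged from 0.000250 to 0.118 for Rbms3, 2.21e-06 to 0.0713 for Axl, 0.000634 to 0.0990 for Tgfb2 and 0.00278 to 0.0979 for Nuak2. Amotl2 and Crim1, chosen after their values were seen and not recomputed without single samples, fell from 9591 ± 1831 to 6204 ± 90.3 and from 3884 ± 466 to 2852 ± 87.8 (adjusted p = 0.0421 and 0.0474). The classical targets, also chosen after their values were seen, did not pass. Cyr61 had 94301 ± 36563 and 47425 ± 255 (adjusted p = 0.117). Ctgf had 16041 ± 3859 and 23892 ± 1159.5 (0.0763) and Ankrd1 24551 ± 4273 and 21919 ± 1595 (0.599). Of 17 Hippo components, Yap1 was the only 1 called (camera adjusted p = 0.956), with a list median of 0.01 and a mean of -0.26 on the log2 scale.

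Several other lists passed camera with few called members. Cell cycle genes had 1 of 16 up (3 adjusted over the list alone; camera adjusted p = 0.000222, and adjusted p = 0.663 with an estimated correlation), and p53 targets 0 of 12 (0 over the list alone; camera adjusted p = 0.00768, and adjusted p = 0.457 with an estimated correlation), both upward. Keratin and junction genes had 1 of 12 up (3 over the list alone; camera adjusted p = 0.0239, and adjusted p = 0.699 with an estimated correlation). Without control 2 their camera adjusted p was 0.371 (range over its alternatives 0.00191 to 0.371). ER stress genes had 0 of 12 (5 up over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.699 with an estimated correlation). Theirs was 0.0984 without control 2 and 0.105 without knockout 1 (range over its alternatives 0.00105 to 0.105). Of the 14 biliary markers, 4 rose and 1 fell (5 and 1 over the list alone; camera adjusted p = 0.162). Cftr, the chloride channel of bile secretion, rose from 3276 ± 1236 to 8916 ± 820.1 (adjusted p = 0.0157). Without knockout 3 that was 0.0821 (range over its alternatives 8.21e-07 to 0.0821). Biliary ion transport and cilia genes had 2 up and 1 down of 12 (2 and 3 over the list alone), with a positive median (0.02) and a downward test (camera adjusted p = 0.831). Haem and iron genes had 1 of 14 up, with a median of -0.03, a mean of 0.01 and a downward test (0.831). Haem oxygenase Hmox1 rose from 294 ± 15.2 to 644 ± 119 (adjusted p = 0.00801). No more than 1 member was called each way in the lists of bile acid synthesis and transport (1 up and 1 down of 14; camera adjusted p = 0.796), NRF2 targets (0 of 8, 2 up over the list alone; 0.268), xenobiotic P450 genes (0 of 4; 0.831), pericentral genes (0 of 9, 3 up over the list alone; 0.200) and the Notch pathway (1 up of 8, 3 over the list alone; 0.538).

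The following 4 lists gained a camera call when a sample was left out. Interferon-stimulated genes (1 of 12 up, 3 over the list alone; 0.0621) passed without control 3 (0.0102), knockout 1 (0.0179) or knockout 2 (0.0357). Immediate-early and dissociation genes (1 of 21 down; 0.0837) passed without control 2 (4.11e-06) or knockout 1 (0.0399). Their fallen member was Dnajb1, from 19697 ± 3854 to 8856 ± 670.0 (adjusted p = 0.00713). Cholesterol synthesis genes (0 of 16; 0.788) passed without control 2 (0.0251). Stellate markers passed without knockout 2 (0.0335; in full 1 up, Rgs5, and 1 down, Reln, of 8; 0.804). The camera adjusted p over each list's alternatives ranged from 0.0102 to 0.378, 4.11e-06 to 0.639, 0.0251 to 0.919 and 0.0335 to 0.909 in that order.

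Markers of other cell types also moved with the knockout. Hepatocyte markers had 1 up, Fgb, and 3 down of 12 (camera adjusted p = 0.0259, and adjusted p = 0.663 with an estimated correlation). That call ended without control 3, knockout 1 or knockout 3 (0.0588, 0.105 and 0.0522) and with quantile normalisation (0.0572). Endothelial markers had 0 of 11 (3 down over the list alone; camera adjusted p = 0.0337, and adjusted p = 0.663 with an estimated correlation). Their adjusted p was 0.0759 without control 1, 0.0550 without control 3 and 0.0557 with quantile normalisation. Mesothelial markers had 2 down of 5 (3 over the list alone; camera adjusted p = 0.0441, and adjusted p = 0.638 with an estimated correlation). Theirs was 0.480 without control 3, 0.105 without knockout 1, 0.0621 without knockout 2 and 0.0619 with quantile normalisation. These 3 lists ranged over their alternatives from 0.000798 to 0.105, 0.00601 to 0.0759 and 0.0122 to 0.480. The macrophage list had 1 of 3 down, the receptor gene Csf1r, from 5483 ± 1059.9 to 1969.8 ± 622 (adjusted p = 0.0120), in cells sorted without CD45 and CD11b. Without knockout 3 its adjusted p was 0.0633 (range over its alternatives 6.70e-08 to 0.0633), and the list's was 0.956. The T and NK list had its 1 measured member, Ccl5, up, the erythroid list 0 of 1, and the neutrophil, B and dendritic lists no measured member.

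**Figure D1:**
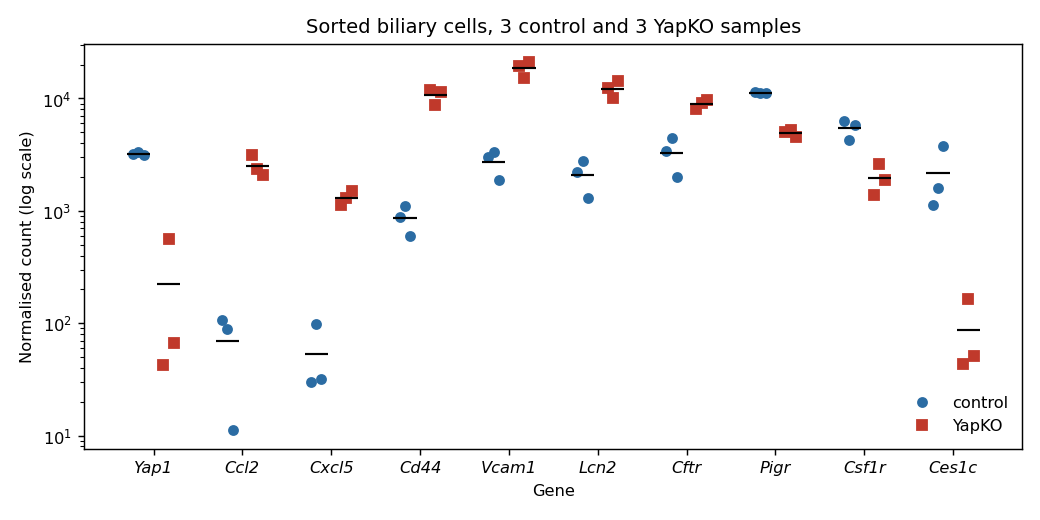
Normalised counts (log axis) of 10 genes in each bulk sample, with control samples as blue circles, Yap1 knockout samples as red squares and group means as black lines. Yap1 lies between 3139.7 and 3324 in controls and between 42.2 and 561 in knockouts, and every knockout value of Ccl2, Cxcl5, Cd44, Vcam1 and Lcn2 lies above every control value.

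The second comparison asked how biliary cells of a mouse on DDC diet differed from those of healthy mice. DDC biliary cells carried far more RNA for many chemokine, matrix, adhesion and cell cycle genes, and less for many immediate-early genes. These cells came mainly from the clusters led by Zfp36 and by Ctla2a, which held almost no control cell. Ccl2 rose from 1.07 ± 1.48 to 1382 (1351 to 1413) CPM (edgeR, log2 fold change 10.22, adjusted p = 1.29e-05) and Ccl20, which attracts lymphocytes and dendritic cells, from 1.57 ± 0.705 to 265 (252 to 279) CPM, 169-fold (adjusted p = 7.50e-06). Mmp7 (chromosome 9), a matrix metalloproteinase, rose from 37.5 ± 6.52 to 1910.4 (1874 to 1947) CPM and Cd44 63.1-fold from 9.53 ± 2.79 to 601 (581 to 622) CPM (adjusted p = 7.50e-06 and 1.29e-05). Yap1 itself had 71.3 ± 5.79 and 70.3 (63.6 to 77.7) CPM (adjusted p = 0.897).

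Of 10911 genes tested, 1621 passed (957 up and 664 down; 836 and 612 by at least 2-fold), and 3284 had an unadjusted p under 0.05. The count was 3110 without control 3 and 489 with the read matrix. Cxcl5 rose from 3.56 ± 3.37 to 551 CPM and the protease inhibitor Slpi from 0.263 ± 0.456 to 102 CPM (adjusted p = 9.38e-05 and 3.32e-05). Ctla2a rose from 0.565 ± 0.594 to 111 CPM, and Cpe, carboxypeptidase E, from 0.899 ± 0.119 to 73.0 CPM. Cdh17 and Csf2, the granulocyte-macrophage growth factor, had 0 counts in the controls and 59.9 and 52.9 CPM in the DDC library, at least 135-fold and 119-fold higher against a floor of 3 counts over the group. Xist (chromosome X), the RNA that silences an X chromosome in females, had 0 counts in the controls and 72.7 CPM in the DDC library, at least 164-fold higher, while Ddx3y (chromosome Y) had 56.7 ± 14.0 and 0 CPM, at least 105-fold lower. The DDC and control mice thus differed in these sex-linked RNAs. Dnajb1, a heat-shock co-chaperone, fell 13.2-fold from 1049 ± 122 to 79.1 CPM and Pigr 13.1-fold from 611 ± 237 to 46.7 CPM (adjusted p = 0.000121 and 0.00155). Fmo2, a flavin monooxygenase, fell from 109 ± 49.3 to 3.59 CPM and the carboxylesterase Ces1d from 1155 ± 345 to 132 CPM (adjusted p = 0.000804 and 0.00127).

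All 16 cell cycle genes rose (camera adjusted p = 2.25e-45, and adjusted p = 0.142 with an estimated correlation; 16 adjusted over the list alone), among them Cdk1, the mitotic kinase, from 5.21 ± 2.05 to 139 CPM and Top2a, topoisomerase II, from 2.39 ± 2.06 to 132 CPM (adjusted p = 5.22e-05 and 9.38e-05). Of 16 reactive duct and matrix genes 14 rose and 0 fell (14 over the list alone; camera adjusted p = 1.74e-32, and adjusted p = 0.142 with an estimated correlation). Vcam1 rose 13.3-fold from 63.0 ± 2.23 to 837 CPM and Pdgfb 13.3-fold from 25.6 ± 1.81 to 341 CPM (adjusted p = 2.22e-05 and 3.25e-05). The chemokine and NF-kB list had 12 of 15 up (14 over the list alone; camera adjusted p = 8.32e-24, and adjusted p = 0.269 with an estimated correlation), with Lif from 10.1 ± 2.78 to 82.7 CPM (adjusted p = 0.000261). Of 21 immediate-early and dissociation genes 15 fell and 1, Ier3, chosen after its values were seen, rose (18 and 1 over the list alone; camera adjusted p = 1.25e-12, and adjusted p = 0.276 with an estimated correlation). Jun fell 5.86-fold from 2835 ± 315 to 484 CPM, Atf3 5.77-fold from 2559 ± 306 to 443 CPM and the heat-shock gene Hspa1b 7.77-fold from 8009 ± 2128 to 1031 CPM (adjusted p = 0.000545, 0.000771 and 0.00105). Acute phase genes had 3 up and 2 down of 10 (4 and 2 over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.412 with an estimated correlation). Over all cells that list had 0.0709 (range over its alternatives 7.57e-05 to 0.0709). Lcn2 rose 21.8-fold from 194 ± 93.9 to 4228 CPM (adjusted p = 0.000158).

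YAP targets moved both ways, with 7 of 19 up and 2 down (the same counts over the list alone; camera adjusted p = 0.230, and adjusted p = 0.706 with an estimated correlation). Ctgf, a matricellular growth factor, rose 3.07-fold from 412 ± 134 to 1266 CPM and Ankrd1 1.82-fold from 718 ± 69.4 to 1303 CPM (adjusted p = 0.00997 and 0.0209). Both were chosen after their values were seen, and their calls were not recomputed under the alternatives. Cyr61 fell 3.19-fold from 3239 ± 556 to 1015 CPM (adjusted p = 0.00541; 0.0533 with the read matrix, range over its alternatives 2.16e-07 to 0.0533). Rbms3 fell 4.19-fold from 154 ± 30.3 to 36.8 CPM and Fjx1 rose from 20.1 ± 3.75 to 56.0 CPM (adjusted p = 0.00319 and 0.00621). Of 16 Hippo components 0 passed (camera adjusted p = 0.812). NRF2 targets of the oxidative stress response had 5 up and 1 down of 8 (7 and 1 over the list alone; camera adjusted p = 0.0257, and adjusted p = 0.412 with an estimated correlation), and interferon-stimulated genes 5 down of 11 (8 over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.549 with an estimated correlation). Car2, carbonic anhydrase, rose from 175 ± 25.7 to 697 CPM and Pkhd1, a protein of cilia, fell from 217 ± 9.49 to 74.1 CPM among 9 ion transport and cilia genes (1 up and 2 down; 0.840). Keratin and junction genes had 4 up and 1 down of 12 (0.230), with Cldn4 from 88.8 ± 21.9 to 300.4 CPM (adjusted p = 0.00357). MHC class II genes had 0 of 5 (camera adjusted p = 0.410; 0.00262 without control 1 and 0.0413 without control 2, range over its alternatives 0.00262 to 0.869). Other process lists had at most 3 members called each way and no camera call (adjusted p 0.0819 to 0.918). Over the list alone, ER stress genes had 1 up and 3 down in place of 1 and 2, Notch genes 1 and 1 in place of 1 and 0, and cholesterol synthesis genes 0 up in place of 1.

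Markers of other cell types moved with DDC as well. Hepatocyte markers had 5 of 10 down (7 down and 1 up over the list alone; camera adjusted p = 0.00536, and adjusted p = 0.447 with an estimated correlation), with Alb from 5065 ± 1114 to 1038 CPM (adjusted p = 0.00296). The fatty acid binding gene Fabp1 had 15.8 ± 11.3 CPM and 0 counts in the DDC library, at least 29.4-fold lower (adjusted p = 0.0141; 0.0668 with the stricter naming of clusters, range over its alternatives 3.08e-08 to 0.0668). Periportal hepatocyte genes had 3 of 8 down (4 over the list alone; camera adjusted p = 0.0415, and adjusted p = 0.412 with an estimated correlation; 0.0718 without control 1 and 0.329 with the stricter naming, range over its alternatives 0.00463 to 0.329). Stellate markers had 2 up and 1 down of 3 (camera adjusted p = 0.00550, and adjusted p = 0.398 with an estimated correlation), with Rgs5 from 20.7 ± 4.26 to 269.7 CPM and Reln from 16.4 ± 5.06 to 1.79 CPM (adjusted p = 5.22e-05 and 0.00651). Of the 14 biliary markers 3 rose and 1 fell (camera adjusted p = 0.287). The comparison rests on 1 DDC mouse.

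**Figure D2:**
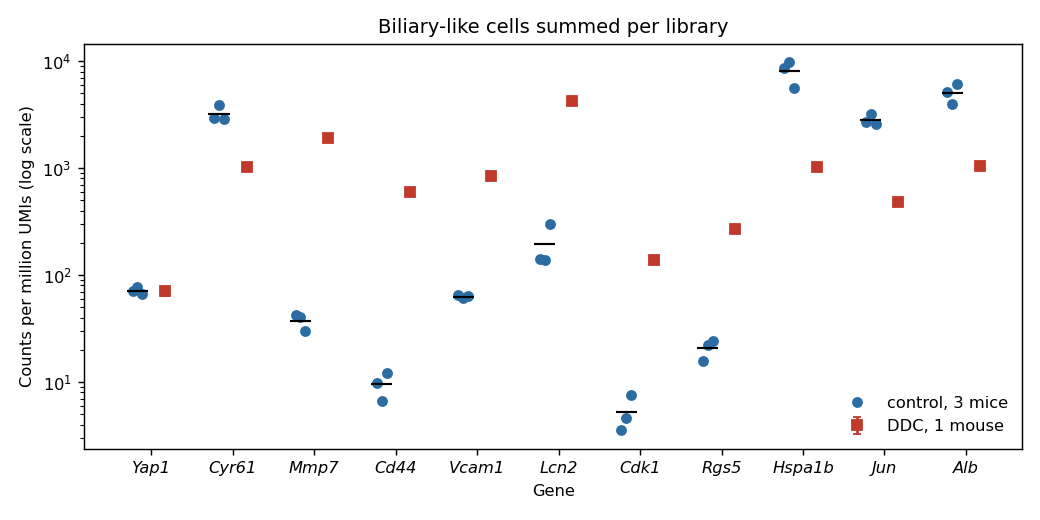
CPM (log axis) of named genes in biliary-like cells, with the 3 control libraries as circles, their mean as a line and the DDC library as a red square with its 95% Poisson interval. The DDC library lies above every control for Mmp7, Cd44, Vcam1, Lcn2, Cdk1 and Rgs5 and below every control for Cyr61, Hspa1b, Jun and Alb.

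**Figure D3:**
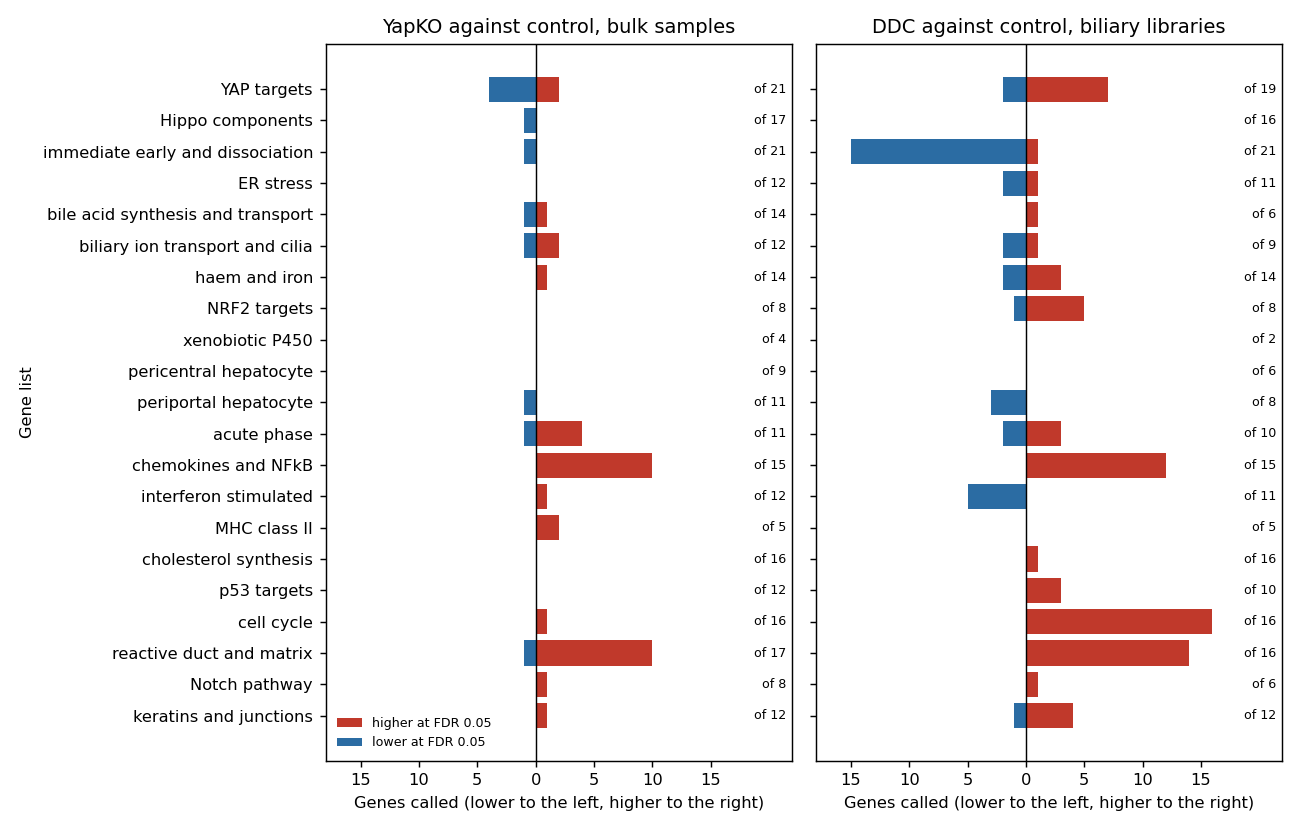
Members of each process list called lower (blue, left) and higher (red, right) in Yap1 knockout bulk samples (left panel) and in DDC biliary cells (right panel), with the number measured beside each bar. The cell cycle list has 1 of 16 members up in the knockout and 16 of 16 up with DDC, and the chemokine list 10 of 15 and 12 of 15 up.

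The third comparison asked how hepatocytes of the DDC-fed mouse differed from those of a healthy mouse. With 1 library per group there is no test, and levels are described with counting intervals (21970844 control and 6490924 DDC UMIs). The DDC and control cells lay almost wholly in separate clusters, and each mouse had a cluster led by rRNA-like genes and a cluster in which mitochondrial genes led or followed Hbb-bs. Reactive duct and matrix genes (9 of 9), cell cycle genes (14 of 14) and NRF2 targets (10 of 10) were higher in the DDC library. Members counted only with at least 5 CPM in either library. Some, such as S100a6 (0.0455 and 48.1 CPM), entered through their DDC level alone, which favours higher members. Genes of secreted male pheromone carriers and 11 of 15 pericentral genes were lower by library total. Gsta1 had 3.82 and 500.2 CPM, 131-fold (105 to 164) higher, and Gstm3 27.8 and 2060.3 CPM, 74.2-fold (68.4 to 80.6) higher. Spp1, osteopontin, had 1.82 and 197 CPM, 108-fold (79.0 to 152) higher. It is a biliary marker, and a share of 1.23% of biliary RNA would bring its rise. Mup15, a major urinary protein, had 2942 CPM in the control and 0 counts in the DDC library, at least 6366-fold lower. The 21 Mup genes summed to 141351 and 8451 CPM, 16.7-fold lower, though their reads are shared between paralogs. Sex-linked RNA did not separate these mice as it did in the biliary comparison. Ddx3y had 72.4 CPM in the control and 108 CPM in the DDC hepatocyte library, and Xist had 1 and 0 UMIs.

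Of 1320 genes with at least 100 CPM in either library, 385 differed by at least 2-fold (243 higher and 142 lower in DDC). The balance depended on scaling and on the mitochondrial filter, without which 385 of 1182 differed (153 higher and 232 lower). That filter removed 2792 of 6000 barcodes in the DDC library and 523 of 6000 in the control library. In the hepatocyte-like cells that were kept, the DDC library had more mitochondrial UMIs (18.4% against 14.6%) and more of rRNA-like genes (9.18% against 2.83%). Mitochondrial rRNA and tRNA made up 26.0% of DDC and 12.9% of control UMIs over all barcodes. In the kept cells they made up 14.4% and 11.8%. The median log2 ratio of the 9100 genes at 5 CPM or more was 0.64 by library total and -0.22 by TMM. By TMM 602 of 1355 genes differed (54 higher), and by a total without mitochondrial and rRNA-like genes, chosen after the values were seen, 596 of 1772 (470 higher). Bst2, Calr, Nfkbia and Wwc1, all under 2-fold, were among the 5 of 101 named genes that had the opposite direction by TMM. Cd63 had 0.683 and 108 CPM, 158-fold (95.1 to 284) higher, the oestrogen sulfotransferase Sult1e1 0.956 and 134 CPM, 141-fold (91.4 to 228) higher, and cyclin Ccnd1 3.19 and 214 CPM, 67.1-fold (52.8 to 86.6) higher. Lcn2 had 3.14 and 219.8 CPM, 70.0-fold (55.0 to 90.5) higher. Slco1a1, an organic anion carrier, had 718 and 2.93 CPM, 245-fold (157 to 407) lower, Elovl3, a fatty acid elongase, 900.4 and 4.01 CPM, 225-fold (153 to 344) lower, and Fabp1 11388 and 778 CPM, 14.6-fold (14.2 to 15.1) lower. Hsd3b5, a steroid dehydrogenase, had 254 CPM and 0 counts, at least 549-fold lower.

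List medians are given as log2 ratios relative to the median of all genes. Reactive duct and matrix genes were highest (3.90; percentile 100.0 among random lists; 9 of 9 at least 2-fold higher), with Lgals3 86.0-fold (57.3 to 135) higher, Anxa2 41.6-fold (30.6 to 58.0) higher and Vcam1 23.6-fold (16.0 to 35.8) higher. Keratin and junction genes lay at 1.22 (percentile 99.985, 6 of 7 higher), where Krt8 had 64.7 and 632 CPM and Krt18 83.9 and 614 CPM. Biliary markers lay at 2.17 (percentile 99.4, 5 of 6 measured members, 4.49 by TMM and 4.47 without the mitochondrial filter). Only 6 of the 14 biliary markers reached 5 CPM. Left out were Epcam (0 and 0.462 CPM), Krt19 (0.0455 and 0.308 CPM) and Cldn7 (0 and 0.616 CPM), among others. NRF2 targets lay at 2.52 (100.0, 9 of 10), with Srxn1 13.6-fold (11.5 to 16.1) and Nqo1 10.7-fold (8.39 to 13.7) higher. Cell cycle genes lay at 2.44 (100.0, 14 of 14), with Top2a 24.5-fold (17.4 to 35.4) higher. Acute phase genes (0.55; 9 of 16 higher), chemokines (1.48; 9 of 11), interferon-stimulated genes (0.98; 6 of 10) and cholesterol synthesis genes (0.49; 8 of 16) also lay above the central 95% of random lists. The interferon list lay at percentile 93.5 without the mitochondrial filter. Pericentral genes lay low (-1.24, percentile 0.305; 5 of 15 at least 2-fold lower), with Cyp2e1 3.51-fold (3.42 to 3.61) lower and Rgn 3.36-fold (3.27 to 3.46) lower, as did bile acid genes (-1.08, percentile 0.590; 5 of 18 lower and 6 higher). Cyp8b1 and Cyp7b1, enzymes of bile acid synthesis, were 18.7-fold (14.9 to 23.8) and 17.1-fold (14.3 to 20.7) lower, while Slc51b, a subunit of the basolateral bile acid exporter, was 64.8-fold (37.9 to 120.1) higher.

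Yap1 had 13.9 and 25.4 CPM, 1.83-fold higher, and the log2 ratio was 0.87 by library total and 0.07 by TMM. Cyr61 had 8.74 and 49.6 CPM, 5.68-fold (4.73 to 6.82) higher. The YAP target list lay at the 96.5 percentile (8 of 12 higher), 83.4 by TMM, 98.9 over all cells and 99.6 by the total without mitochondrial and rRNA-like genes. Between the limits by library total were periportal genes (95.5; 97.8 by TMM), MHC class II (94.1; 99.8 over all cells), p53 targets (92.5), xenobiotic P450 genes (89.2), the Notch pathway (88.3), Hippo components (68.2), biliary ion transport (66.2), immediate-early genes (65.3), haem and iron (43.4) and ER stress (12.9). Within the P450 list Cyp2b10, induced by constitutive androstane receptor activators, had 8.97 and 330.3 CPM, 36.8-fold (31.8 to 42.8) higher, and within the haem list Hmox1 had 1.55 and 32.5 CPM, 21.0-fold (14.6 to 31.1) higher. Markers of other cell types were higher too, the macrophage list at 2.14 (percentile 100.0; 11 of 11), the stellate list at 3.07 (100.0; 9 of 9) and the neutrophil and monocyte list at percentile 99.8 (3 of 3; 94.2 at 1000 UMIs), with Lyz2 at 17.3 and 135 CPM and Dcn at 9.97 and 120.5 CPM. Erythroid markers were lower (-4.39, percentile 0.0150; 3 of 3), and hepatocyte (14.4) and endothelial (87.2) markers lay between.

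**Figure D4:**
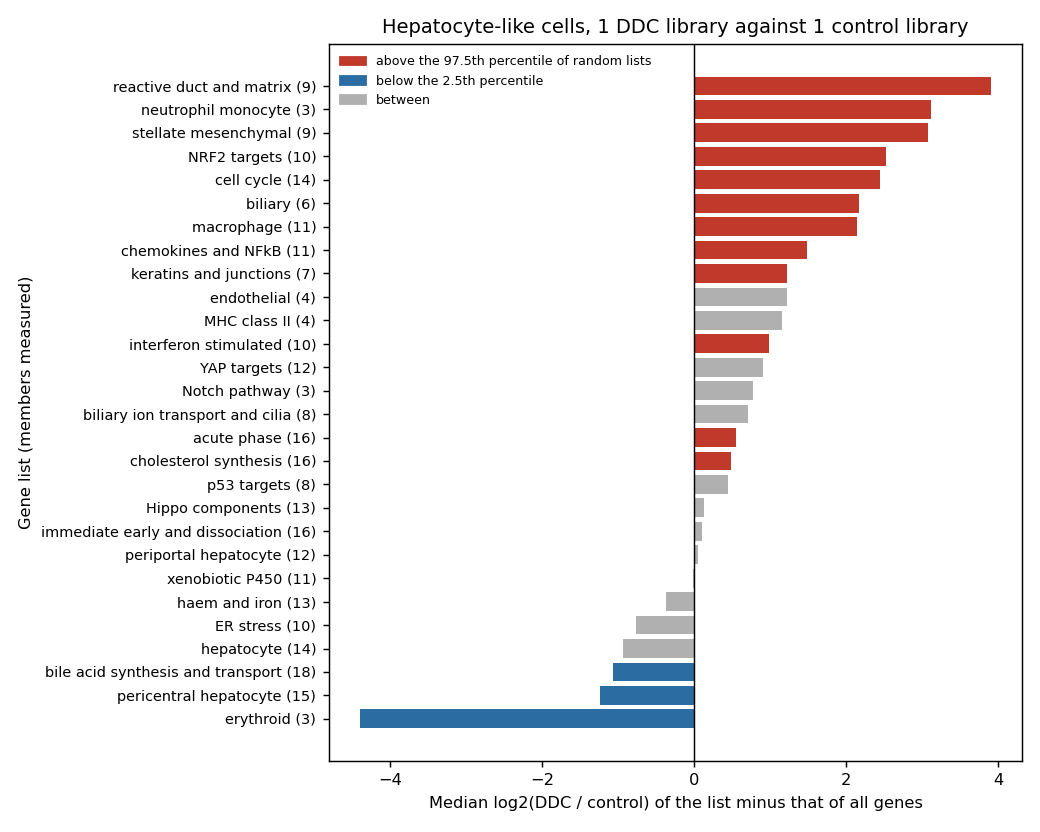
Median log2 ratio (DDC over control) in hepatocyte-like cells, minus that of all genes, of each process or cell type list with at least 3 members measured. The number of members measured is in brackets. Red bars lie above and blue bars below the central 95% of random lists, and grey bars within it. Reactive duct and matrix genes reach 3.90, pericentral genes -1.24 and erythroid markers -4.39.

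The fourth comparison asked which genes separate healthy biliary cells from healthy hepatocytes, and where YAP targets lie between them. YAP targets were mostly biliary: 13 of 17 were lower in HEP and 2, Dock5 and Nt5e, chosen after their values were seen, higher (the same over the list alone; camera adjusted p = 1.11e-06, and adjusted p = 0.196 with an estimated correlation). Ankrd1 had 725 ± 69.8 and 0.0522 CPM in BEC and HEP, F3, tissue factor, 302 ± 33.9 and 1.52 CPM and Myof, a membrane repair protein, 106 ± 14.3 and 0.209 CPM (adjusted p = 2.58e-07, 8.89e-07 and 8.12e-07). Yap1 had 72.0 ± 5.83 and 16.0 (14.2 to 17.9) CPM, with a log2 fold change of -0.75 after TMM (adjusted p = 0.0220; 0.0823 without control 1 and 0.0504 by the DESeq2 Wald test, range over its alternatives 0.00461 to 0.0823). Notch genes were all lower in HEP, 6 of 6 (6 over the list alone; camera adjusted p = 0.00822, and adjusted p = 0.220 with an estimated correlation), with Hes1 at 1827 ± 360.0 and 13.1 CPM. Of 10789 genes, 3724 were higher and 3672 lower in HEP, and 7692 had an unadjusted p under 0.05. TMM factors were 1.24 to 1.31 in BEC and 0.478 in HEP, so fitted changes are relative to most genes and not to CPM.

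All 12 biliary markers were lower in HEP (camera adjusted p = 1.31e-10, and adjusted p = 0.196 with an estimated correlation) and all 14 hepatocyte markers higher (camera adjusted p = 3.86e-09, and adjusted p = 0.206 with an estimated correlation), with the same counts over each list alone. Epcam, the adhesion molecule used to sort the bulk samples, had 783 ± 71.6 CPM in BEC and 0 counts in HEP, at least 4993-fold lower. Sox9, the duct transcription factor, had 1120.1 ± 84.0 and 3.34 CPM. Cyp2c50 and Slco1a1 had 0 counts in BEC and 1015 and 824 CPM in HEP, at least 2260.0-fold and 1835-fold higher. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0.149 ± 0.257 and 247 CPM, and Cps1, of the urea cycle, 0.297 ± 0.515 and 1791 CPM. Camera placed higher in HEP the lists of bile acid genes (15 of 17, 1 lower), xenobiotic P450 genes (9 of 9), pericentral (14 of 15), periportal (9 of 12, 1 lower) and acute phase genes (12 of 13, 1 lower), with adjusted p of 1.00e-15 to 1.35e-07 and adjusted p of 0.196 to 0.206 with an estimated correlation. Haem and iron genes (11 of 14, 2 lower, or 3 lower over the list alone) had 0.00594 and 0.317 likewise, and macrophage markers (6 of 7, 1 lower) 0.0258 and 0.435, not passing without control 2 (0.05005) or with the stricter naming (0.131; range over its alternatives 0.00200 to 0.131). Lists lower in HEP were immediate-early and dissociation genes (21 of 21), keratins and junctions (11 of 11), biliary ion transport and cilia (8 of 9), reactive duct and matrix (11 of 12, 1 higher) and chemokines (10 of 12), with camera adjusted p of 5.95e-11 to 0.000709 and adjusted p of 0.196 to 0.317 with an estimated correlation. The comparison sets 3 mice against 1, and isolation, barcode layout and gene annotation differ between the cell types. Across control biliary cells the YAP target score rose with the immediate-early and dissociation score (correlations of 0.304 to 0.379). The part of isolation in the higher YAP targets and dissociation genes of BEC was not tested.

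The last comparison asked whether YAP targets vary together among single biliary cells. At 1000 UMIs per cell the mean pairwise correlation across cells was 0.0243, 0.0216 and 0.0185 in controls 1 to 3 (13, 14 and 13 genes; 1224, 1246 and 1291 cells) and 0.0161 in the DDC mouse (17 genes, 1506 cells). Each value lay at the 100th percentile of 1000 random lists, whose medians lay between -0.00014 and 0.000237. Without Cyr61 and Ctgf the values were 0.0108, 0.0129, 0.00903 and 0.00827. The following genes were chosen after their values were seen. Ctgf had a UMI in 20.8%, 14.1% and 26.1% of control cells and 57.8% of DDC cells. In the separate hepatocyte libraries the shares were 0.0186% (control) and 0.418% (DDC). Background within the biliary libraries was not measured. Ankrd1 was seen in 22.8%, 24.8% and 22.6% of control and 46.6% of DDC biliary cells, against 0% of control and DDC hepatocytes. Cyr61, by contrast, was seen in 62.6%, 64.2% and 59.7% of control and 47.3% of DDC biliary cells, against 1.04% and 4.56% of hepatocytes. Cd44 was seen in 0.98%, 0.482% and 1.08% of control and 37.0% of DDC biliary cells, against 0.0372% and 1.84% of hepatocytes. All shares were taken at 1000 UMIs per cell; before thinning the median depths were 1756, 1357, 1698 and 3498.5 UMIs in biliary-like cells and 3049 and 1425 in hepatocyte-like cells.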

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

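Of the tests in this part, the one of macrophage RNA as a source of Cd44, Vcam1 and Vim was chosen after the result was seen.

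The changes in the DDC biliary library came with a difference in sex-linked RNA, since that library alone among the BEC libraries carried Xist (72.7 CPM) and had 0 CPM of Ddx3y against 45.0 to 72.3 CPM in the controls. If sex were the main source, biliary cells of the female bulk controls should differ from the Ddx3y-positive single-cell controls in the 1545 called genes tested in both assays by nearly as much as the DDC library does. The gap between called-up and called-down genes was 0.23 for bulk controls against 3.11 for the DDC library on the log2 scale, or 7.46% of it (95% bootstrap interval over genes 3.02 to 11.8), which argues against sex as the main source, although bulk and single-cell values also differ by assay. Sex stays open for single genes, Xist and Ddx3y among them. The diet, the individual mouse and its library go together in 1 DDC library, so these remain open and untested.

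Keratin, junction, duct and matrix genes were higher in the DDC hepatocyte library, which also held more RNA of macrophage markers, such as Lyz2 (17.3 and 135 CPM) and Cd5l (4.23 and 58.4 CPM), and of stellate markers, such as Dcn (9.97 and 120.5 CPM), whose list lay higher (3.07 against 2.14 on the log2 scale relative to all genes). With RNA from biliary cells, the median of 9 biliary markers would need a share of 0.918% and the median of the 15 genes 9.81%. In all, 14 of the 15 genes needed over 3 times the marker share, counting Tgfbi, which had no UMI in the source. This argues against biliary RNA as the common source. The exception was S100a6 (1.44%), for which biliary RNA stays open, as it does for the marker Spp1 (1.23%). RNA from macrophages, taken from the 128 DDC cells of the cluster with macrophage genes, would need 2.29% by the 11 markers and 28.6% by the genes, and 12 of 15 genes, counting Ocln with no UMI there, needed over 3 times the marker share, which argues against it too. The other 3, Cd44, Vcam1 and Vim (5.62%, 4.22% and 4.53%), were picked by that limit, so their shares test nothing, and macrophage RNA cannot be told apart from expression in hepatocytes for them at 1 library per group. RNA from stellate cells, for which no cluster was named, and the diet as a biological explanation remain untested, and no sort of these cells is given in the sources used here.

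YAP targets varied together among biliary cells, and their score rose with that of immediate-early and dissociation genes, with correlations across cells of 0.368, 0.379 and 0.304 in controls 1 to 3 and 0.194 in the DDC library. If dissociation were the whole source and the immediate-early score held it all, removing that score would put the list among random lists. The list stayed above the 95th percentile in 4 of 4 libraries, with mean correlations of 0.0139, 0.0116, 0.0126 and 0.0140 (57.3%, 53.6%, 68.3% and 86.9% of the values before). A part of the values was thus lost with that score. At 1000 UMIs per cell the score is noisy, and removing it can leave a part of the response behind. What remained therefore does not decide whether dissociation is the whole source. Shared variation in YAP activity is a hypothesis from the same cells, and it was not tested, since YAP activity was not measured. In the Yap1 knockout bulk samples this list did not move as a group (2 of 21 members up and 4 down, camera adjusted p = 0.804). Other programmes that the score does not hold were not tested.

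The following 10 genes were called in DDC biliary cells and differed by at least 2-fold the opposite way in DDC hepatocytes by library total. Every difference was set between 1 DDC library and its controls in each cell type, and the differences themselves were not tested. The log2 change was -4.83 in biliary cells and 2.82 in hepatocytes for Fmo2, a difference of 7.64. For Alb it was -2.22 in biliary cells and 1.07 in hepatocytes (difference 3.29). Reln had -3.09 in biliary cells and 4.31 in hepatocytes (difference 7.40), from low levels in hepatocytes (1.14 and 23.0 CPM). It is a stellate marker, and all 9 measured stellate markers were at least 2-fold higher in the DDC hepatocyte library. Cyr61 had -1.60 in biliary cells and 2.50 in hepatocytes (difference 4.10). Klf6 had -1.34 in biliary cells and 3.82 in hepatocytes (difference 5.15) and Egr1 -1.48 in biliary cells and 1.09 in hepatocytes (difference 2.58). Gstm1 had -1.12 in biliary cells and 3.39 in hepatocytes (difference 4.50). Pck1 had -6.93 in biliary cells and 1.04 in hepatocytes (difference 7.97), where the biliary value rests on 0 UMIs in the DDC library and so on the prior count. Sdf2l1 went the other way, with 1.98 in biliary cells and -1.03 in hepatocytes (difference -3.02), as did Abcg2, with 1.72 in biliary cells and -1.25 in hepatocytes (difference -2.97). The 2-fold size in hepatocytes depended on scaling for some. By TMM the log2 ratio was 0.27 for Alb, 0.24 for Pck1 and 0.30 for Egr1. By the total without mitochondrial and rRNA-like genes, chosen after the values were seen, it was -0.84 for Sdf2l1. Alb and Pck1 belong to the hepatocyte and periportal lists, whose median log2 changes in DDC biliary cells were -2.64 and -2.72. RNA from other cells as a source of these differences was not tested.

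An eGFP transgene was listed in the DDC and control 3 biliary libraries and absent from the others, and the labels name no reporter. Over all cells of the DDC library 117 of 1682 (6.96%) held 295 UMIs, at most 33 in a cell, and 24 cells of control 3 held 33 UMIs. In biliary-like cells the level was 52.2 CPM in the DDC library, 11.4 CPM in control 3 and 0 in controls 1 and 2, which allows up to 1.32 and 1.54 CPM. eGFP was 1 of the genes tested between these groups (edgeR adjusted p = 0.0245), but no gene list or rule named it, its call was not recomputed without single libraries, and its cells were not analysed apart.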

How the results depend on the processing

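In this part, the count of sample splits, the stricter naming of clusters and the hepatocyte library total without mitochondrial and rRNA-like genes were chosen after the results were seen.

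Direction was compared for named genes and lists, and no list or named gene that was called, and 0 of 91 named hepatocyte genes at 2-fold, reversed it. With DESeq2 on the recovered reads the bulk count was 1961 in place of 1179, and leaving out each sample gave 237 to 1056 genes; the other bulk alternatives stayed within a factor of 1.5, and the 11 lists called became 8 to 12. Of 10 splits of the 6 bulk samples into 3 and 3, the real one called 1179 genes and the highest other 0, with 1 split as large as the real one; 10 splits are too few for a share under 0.05. Among 60 named bulk genes called, 30 kept their call under every alternative, and leaving out knockout 3 or knockout 1 ended the most calls of genes and lists (28 and 21). For DDC biliary cells the read matrix gave 489 genes in place of 1621, and leaving out each control gave 1194 to 3110, the highest without control 3; the other alternatives stayed within a factor of 1.5, the lists called numbered 9 to 11, and 50 of 86 named genes kept their call throughout. For biliary cells against hepatocytes, 101 of 110 named genes and 15 of 16 lists did. Fewer samples remain when 1 is left out, yet the DDC biliary count rose without control 3. The cause was not tested for samples left out, DESeq2 or the read matrix.

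In DDC hepatocytes TMM scaling gave 602 genes at 2-fold and the total without mitochondrial and rRNA-like genes 596, in place of 385. Each moves every ratio by a common factor and also changes which genes reach 100 CPM (1355 and 1772 genes, in place of 1320). With no mitochondrial filter the count stayed at 385, but 153 were higher in place of 243, and the cause was not tested. Of 606 values for 101 named genes under the alternatives, 210 moved beyond their counting interval. By TMM 5 genes, none of them 2-fold, turned direction and 12 of 91 at 2-fold fell below it, 13 under any alternative, and 6 of 166 list percentiles changed band. With at least 1000 UMIs per cell, and again with no mitochondrial filter, the biliary-like share was 100% in each of the 4 biliary libraries, since no biliary cluster was then left unnamed. The hepatocyte-like share of the DDC library was 96.7% with no mitochondrial filter and 97.2% at Leiden resolution 0.5, and the cause was not tested. With clusters left unnamed where any marker of another class was among the 10 leading genes, the named share was 77.4%, 72.6% and 68.7% in biliary controls 1 to 3 and 69.0% in the hepatocyte control, since a cluster with Ttr and a cluster with Hbb-bs among these genes lost their names. The count of genes was then 1603 in DDC biliary cells and 7175 between the cell types, and 385 hepatocyte genes differed by 2-fold. The co-variation of YAP targets stayed above the 95th percentile in 4 of 4 libraries under its 3 alternatives. No paired analysis was possible because the control columns are not mapped to single samples and the labels pair no animals. Depth limits the hepatocyte comparison to genes above the floor of 0.137 CPM (control) and 0.462 CPM (DDC), and the biliary floors were 0.538 CPM (DDC) and 1.18 to 1.54 CPM per control.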

Other observations

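Of the tests in this part, the overlap between the Yap1 knockout and the DDC diet was chosen after the results were seen.

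Biliary cells held UMIs of a pair of hepatocyte genes to different extents. At 1000 UMIs per cell, Alb, serum albumin, had a UMI in 94.9%, 88.8% and 95.5% of biliary-like cells of controls 1 to 3 and in 44.9% of DDC cells, against 99.9% and 100% of control and DDC hepatocytes. Apoa1, an abundant apolipoprotein of hepatocytes, had a UMI in 6.45%, 0.0803% and 0.387% of control and 0.0664% of DDC biliary cells, against 99.3% and 99.2% of hepatocytes. Median depths before thinning were 1756, 1357, 1698 and 3498.5 UMIs in biliary-like and 3049 and 1425 UMIs in hepatocyte-like cells.

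Cell division genes were seen in few cells. Top2a had a UMI in 0.163%, 0.0803% and 0.232% of control and 8.10% of DDC biliary cells, and in 0.279% of control and 3.81% of DDC hepatocytes. Mki67, a marker of dividing cells, had a UMI in 0%, 0.161% and 0.155% of control and 4.52% of DDC biliary cells and in 0.168% and 3.18% of control and DDC hepatocytes. In the bulk samples, Gt(ROSA)26Sor, the transcript of a locus widely used for transgenes, fell from 799.7 ± 113 to 127 ± 83.2 (limma adjusted p = 0.0253). Its adjusted p was 0.0666 without control 1, 0.0544 without control 2 and 0.0566 without the trend in limma (range over its alternatives 0.00190 to 0.0666); the knockouts also carried the CAGs-rtTA3 transgene, which the controls lacked.

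A hypothesis from the values above is that biliary cells lacking Yap1 and biliary cells of a DDC-fed mouse change some of the same genes in the same direction. Of 10332 genes tested in both comparisons, 963 were called in the knockout (547 up and 416 down) and 1545 with DDC (911 up and 634 down). The 521 called in both were 54.1% of the knockout calls and 33.7% of the DDC calls, and the rest had a call in 1 comparison alone. Among these 521, which were picked by their calls, 516 (99.0%) went the same way. Up in both were 294 genes, against 48.2 if the calls were independent, and down in both 222, against 25.5. Opposite calls numbered 3 and 2, against 33.6 and 36.7, and the genes were Rassf3, BC016579 and Gbp8, and Nuak2 and Mylk, chosen after their values were seen. Ccl2, Cxcl5, Cd44, Vcam1, Il1rn and Akap12 were among those up in both, and Tbxas1, Hao2, Ces1c and Cldn10 among those down in both. Across genes the log2 changes had a Pearson correlation of 0.679 and a Spearman correlation of 0.618, and genes are not independent replicates. The comparisons share no samples, and the bulk mice were all female, so a sex difference would not enter the bulk changes. The overlap is consistent with a shared inflammatory and duct-injury response, which may follow from injury in the knockout livers rather than from Yap1 itself, and no further test was run.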
